A study of Mus musculus with 13 samples.

How the data were processed

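RNA was sequenced from the cortex of 13 male mice aged 18 months. The labels give 3 genotypes: 5 wild-type mice (Grn+/+), 4 mice with 1 copy of the mouse progranulin gene (Grn+/-), and 4 mice that lack mouse Grn and carry a human GRN transgene (Grn-/-;GRNtg). Libraries were made from total RNA with a directional kit, per the labels' protocols. Genome build mm10, R 4.1.2 and DESeq2 1.34.0 were used by the authors, per the submitters' processing notes, which name no role for each. The aligner, the read counter, the annotation and the strand setting of the counting are not given in the sources used here. Genes that overlap another gene or an antisense transcript are therefore uncertain where their reads can be shared, and mouse Grn itself overlaps Fam171a2 on the opposite strand.

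The files used here are the authors' own comparison tables, with no values per mouse. Each table gives, per the file headers, a mean normalized count, which is a signal averaged over libraries by the authors. Each also gives the authors' log2 fold change with its standard error (SE), per the file headers. The Wald statistic is a score that the authors computed as the log2 fold change over its SE, and division of the deposited columns returned it in every row. The p-value and the adjusted p-value are the authors', and the Benjamini-Hochberg adjustment of the deposited p-values over each table's rows returned the deposited adjusted values. Fold changes of the 3 tables add up exactly, so they come from a single fit. Deposited SEs share a ceiling of 0.138 in all 3 tables, as a zero-centred prior on fold changes would give. Whether the authors used such a prior is not given in the sources used here, and fold changes of genes with few reads are drawn towards 0 if they did. The tables list 13482, 14961 and 17562 genes for Grn+/- against wild type, Grn-/-;GRNtg against wild type and Grn-/-;GRNtg against Grn+/-, and 13482 genes stand in all 3. The lowest mean normalized count in them was 24.7, 6.83 and 0.523. A further 2 rows name no gene and were left out of every test. Reads assigned to no gene (no_feature) made up 17.0% of the mean normalized counts and ambiguous reads 0.606%. Whether the former include reads of introns or of the other strand is not known, since the counting is not described.

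Depth per mouse is not known from these tables. Mean normalized counts of genes summed to 18113972 per library, or 21982595 with the 2 other rows. The deposited SE is the only measure of precision, and a small SE need not mean many reads. In Grn-/-;GRNtg against Grn+/-, Serpina1e had an SE of 0.023 at a mean normalized count of 0.823 in the authors' deposited table. Grn had an SE of 0.085 at a mean normalized count of 784 there. The p-values of single genes measure the spread between these mice, as the authors' model gives it. Those of the gene list tests set the statistics of genes against each other. They do not measure spread between mice directly. No label gives a batch, a litter or a dissection day, so none of these can be separated from genotype.

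A gene counted as changed where the authors' adjusted p was under 0.05. Gene lists were compared with all other genes of a table by the competitive set test cameraPR of limma 3.58.1 in R 4.3.3, on the Wald statistic, two-sided, with a preset inter-gene correlation of 0.01. Lists needed at least 5 measured members, and p-values were adjusted by Benjamini-Hochberg over all lists and the 3 comparisons. No correlation could be estimated without values per mouse, so the test was repeated at a preset correlation of 0.05. The 33 lists held 750 entries, of which 713 matched a gene in the tables, 2 of them under an older or alternative symbol. The list of mitochondrially encoded genes had 0 matches and was not analysed here. It was fixed as a sign of RNA quality, as were the lists of nuclear-retained RNAs and of cytosolic ribosome genes. The lists of striatum, hippocampus, thalamus, choroid plexus, leptomeninges and blood were fixed as markers of tissue that a cortex dissection could hold. A different cut of the tissue cannot be told apart from a change of expression in these lists. Members of each list were also counted after adjustment over the list alone. Fold changes of the mutant groups against the same wild-type mice share chance values. Their correlation, covariance and overlap were therefore set beside 100 simulations of unchanged groups, with the shared variance of each gene taken from its SEs in the 3 tables and genes drawn independently of each other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, and 98.8% of the genes had one.

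Groups, tests, lists, the rule for named genes and the other settings listed in advance were fixed before the data were examined. The rule takes, in each comparison, Grn, the 10 higher and 10 lower genes with the smallest adjusted p among genes that pass and have a mean normalized count of at least 10, and up to 4 members with the smallest p of each list that passes. It takes the same number from the lists of homeostatic microglia, disease-associated microglia, lysosome, complement, reactive astrocyte and neighbours of Grn in any case. Values of 1 gene that the rule takes are not reported here. The lists of liver, kidney, skeletal muscle, skin and pancreas genes were written after liver genes were seen among the calls. Alternatives changed the threshold, the minimum count, the adjustment, a minimum fold, the centring, the null distribution and the settings of the set test. Alternatives chosen after seeing the data left out liver genes or Grn, removed a trend of the statistic with gene span, or removed a prior from the Grn fold change.

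The steps were tested on simulated data made from the SEs of the 13482 shared genes. For Grn-/-;GRNtg against Grn+/-, 48% of genes given a log2 change of 0.3 and 92% of those given 0.6 were called with their direction, and 5.92% of calls had no change put in. A list shifted on purpose passed with adjusted p = 9.93e-12, and 0 of 91 other list tests passed. Genes were drawn independently of each other, so this does not cover lists whose members vary together. Values were drawn with the same SEs that gave their p-values, so the share of false calls was set near the threshold by construction. It does not test the authors' p-values. The changes put in were not drawn towards 0, so the rates of detection are too high if the deposited fold changes were. Genes outside the 13482 were not simulated. A shared covariance of 0.01 put into both mutant groups was returned as 0.00985.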

Results

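Cortical RNA was compared between 18-month-old male mice of 3 genotypes: 5 wild-type mice, 4 Grn+/- mice and 4 Grn-/-;GRNtg mice. Grn encodes progranulin, a secreted and lysosomal glycoprotein, and loss of 1 copy of the human gene causes frontotemporal dementia. The Grn-/-;GRNtg mice carry human GRN in place of the mouse gene and are described in the labels as humanized and progranulin deficient. All fold changes and adjusted p-values of single genes are from the authors' deposited tables, where the error is the SE of the log2 fold change.

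Mouse Grn (chromosome 11, 102430315 to 102437048, plus strand, GRCm38) had a mean normalized count of 784 in the authors' deposited tables. Its transcript fell in Grn+/- against wild type, with a log2 fold change of -0.65 ± 0.077 and adjusted p = 2.9e-13 in the authors' deposited table, or 63.6% of the wild-type level. In Grn-/-;GRNtg it fell to 24.7% of wild type, a log2 fold change of -2.02 ± 0.081 with adjusted p = 5.8e-131 in the authors' deposited table. Between the mutant groups the authors' deposited table gives -1.36 ± 0.085, with adjusted p = 5.2e-53. Grn was the only gene called in all 3 tables.

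The comparison of Grn+/- with wild type asks what loss of 1 mouse Grn copy does to the aged cortex. Immediate early genes, which neurons induce with activity, were lower: 6 of 28 measured members fell, and 10 when adjusted over the list alone. Homer1 fell by 0.51 (SE 0.111), Klf4 by 0.58 (SE 0.135), Nr4a3 by 0.58 (SE 0.137) and Atf3 by 0.57 (SE 0.13) on the log2 scale in the authors' deposited table. Nuclear oxidative phosphorylation genes were higher, with 44 of 48 members positive, 3 passing and 6 when adjusted over the list alone. Ndufv2 (0.23 ± 0.056), Ndufb10 (0.20 ± 0.050) and Sdhd (0.18 ± 0.060), subunits of respiratory complexes, rose in the authors' deposited table. Set tests gave adjusted p = 4.6e-07 for immediate early genes and 1.3e-06 for oxidative phosphorylation.

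Noncoding RNAs kept in the nucleus fell as a list (set test adjusted p = 0.00015), with 4 of 11 members lower and 5 when adjusted over the list alone. The list was fixed as a sign of RNA quality, so a difference in RNA between the groups cannot be told apart from genotype here. Mirg (-0.45 ± 0.086), Malat1 (-0.43 ± 0.109), Kcnq1ot1 (-0.42 ± 0.101) and Rian (-0.23 ± 0.066) fell in the authors' deposited table. Reads assigned to no gene were also lower, at -0.22 ± 0.052 with adjusted p = 0.0019 in the authors' deposited table. Astrocyte markers fell as a list (adjusted p = 0.0011), with 4 of 16 members lower over all genes and 4 when adjusted over the list alone. Among them Ppp1r3c had -0.41 ± 0.113, Gja1 -0.26 ± 0.085, Slc4a4 -0.25 ± 0.080 and Slc1a2, the main glutamate transporter of astrocytes, -0.22 ± 0.073 in the authors' deposited table. Cholesterol synthesis genes were higher as a list (adjusted p = 0.0011), with 1 of 22 passing and 4 when adjusted over the list alone.

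A further 5 lists passed with a correlation of 0.01 and not with 0.05. Endoplasmic reticulum stress genes were lower (adjusted p = 0.015, and 0.11 at 0.05), with 5 of 20 members lower, and with 7 lower and 1 higher when adjusted over the list alone. Xbp1 (-0.29 ± 0.058), Creld2 (-0.39 ± 0.091), Pdia4 (-0.32 ± 0.085) and Dnajc3 (-0.23 ± 0.070) fell in the authors' deposited table. Myelin genes were negative in 20 of 20 members with 0 passing, also when adjusted over the list alone (adjusted p = 0.020, and 0.12 at 0.05). Oligodendrocyte precursor genes were lower (adjusted p = 0.043, 0.15 at 0.05, and 0.062 with a trend with gene span removed) with 2 of 15 passing, and 2 when adjusted over the list alone, Gpr17 at -0.49 ± 0.094 and Vcan at -0.45 ± 0.108 in the authors' deposited table. Leptomeningeal markers were higher with 0 of 21 passing, also when adjusted over the list alone (adjusted p = 0.010, and 0.088 at 0.05). Lysosome genes were higher as a list (adjusted p = 0.049, 0.27 at 0.05, and 0.072 with that trend removed) with 1 of 42 passing, and 1 when adjusted over the list alone: Psap, which encodes prosaposin, at 0.15 ± 0.042 in the authors' deposited table.

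Microglial lists did not pass. Homeostatic microglia genes had adjusted p = 0.15 with 1 of 18 lower, and 1 when adjusted over the list alone: Tgfbr1 at -0.30 ± 0.099 in the authors' deposited table. Disease-associated microglia genes had adjusted p = 0.48 and 0 of 18 passing, also when adjusted over the list alone, with Gpnmb at 0.27 ± 0.138 and Ctsb at 0.18 ± 0.069 in the authors' deposited table. Complement (adjusted p = 0.70) held Cfp, properdin, which fell by 0.46 (SE 0.105) in the authors' deposited table, and reactive astrocyte genes (adjusted p = 0.57) held Nes, which fell by 0.46 (SE 0.129) there. Each was the only member of its list to pass, and 1 passed in each when adjusted over the list alone. Neighbours of Grn on chromosome 11 had adjusted p = 0.97 in the set test, which looks for a common direction. Of 41 members, 3 were higher and 2 lower, and the same numbers when adjusted over the list alone. Of all 13482 genes, 917 passed.

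Outside the lists, Dok6 (-1.05 ± 0.135), Zfp369 (-0.86 ± 0.136), Nbeal1 (-0.84 ± 0.133), Ago3 (-0.80 ± 0.137) and Prex2 (-0.73 ± 0.119) were among the lowest in the authors' deposited table. Pvrl1 (-0.42 ± 0.056), Tra2a (-0.43 ± 0.066), Ccnt2 (-0.45 ± 0.074) and Fnbp1l (-0.46 ± 0.077) fell with smaller SEs in the authors' deposited table. Wnt9a (0.50 ± 0.099), Slitrk1 (0.45 ± 0.079), Sh2d3c (0.40 ± 0.088), Fbxo34 (0.38 ± 0.082) and Zdhhc8 (0.33 ± 0.064) rose in the authors' deposited table. Oprl1, the nociceptin receptor (0.33 ± 0.069), Tceal5 (0.32 ± 0.066), Actr3b (0.29 ± 0.059), Nudt18 (0.28 ± 0.057) and Ppm1g (0.23 ± 0.050) rose there too, in the same authors' deposited table. Of 13482 genes, 917 passed in the authors' deposited table, 309 higher and 608 lower. With the statistics divided by their robust spread, 3 genes passed, and with a minimum absolute log2 fold change of 0.3, 499 did.

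**Figure D1:**
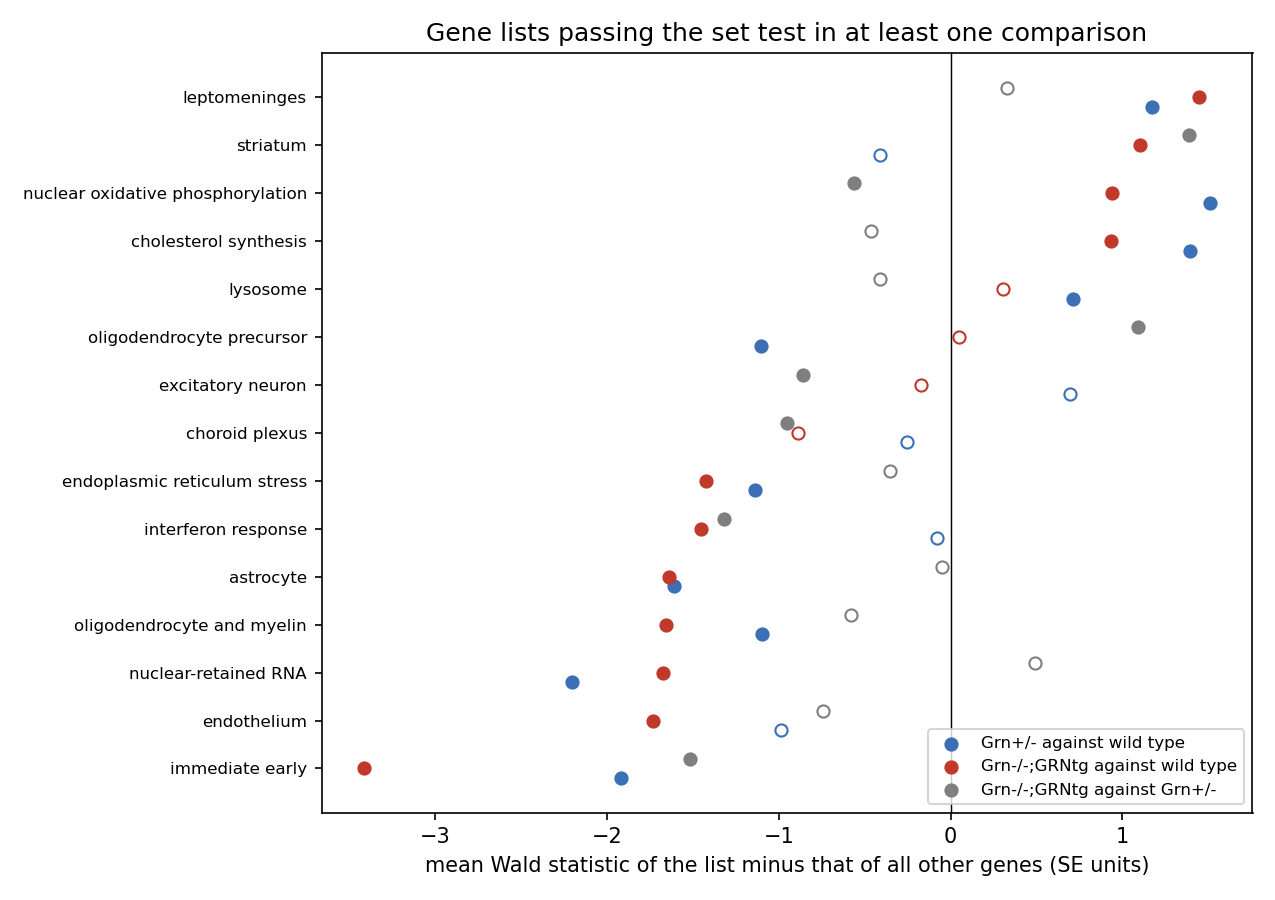
Mean Wald statistic of each gene list minus that of all other genes, in SE units, for lists that passed the set test in at least 1 of the 3 comparisons; filled points passed an adjusted p of 0.05 and open points did not. Immediate early genes lie farthest below 0 in Grn-/-;GRNtg against wild type, at -3.42.

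The comparison of Grn-/-;GRNtg with wild type asks what replacing mouse Grn by the human transgene does. Immediate early genes were lower here too, in 18 of 28 members over all genes and 22 when adjusted over the list alone (set test adjusted p = 1.8e-22). Trib1 fell by 0.89 (SE 0.129), Klf2 by 0.77 (SE 0.135), Ier2 by 0.75 (SE 0.134) and Dusp6, a phosphatase of the ERK pathway, by 0.73 (SE 0.111) on the log2 scale in the authors' deposited table. The median log2 fold change of the list was -0.49. Hif3a (0.93 ± 0.137) and Fkbp5 (0.58 ± 0.112) rose in the authors' deposited table.

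**Figure D2:**
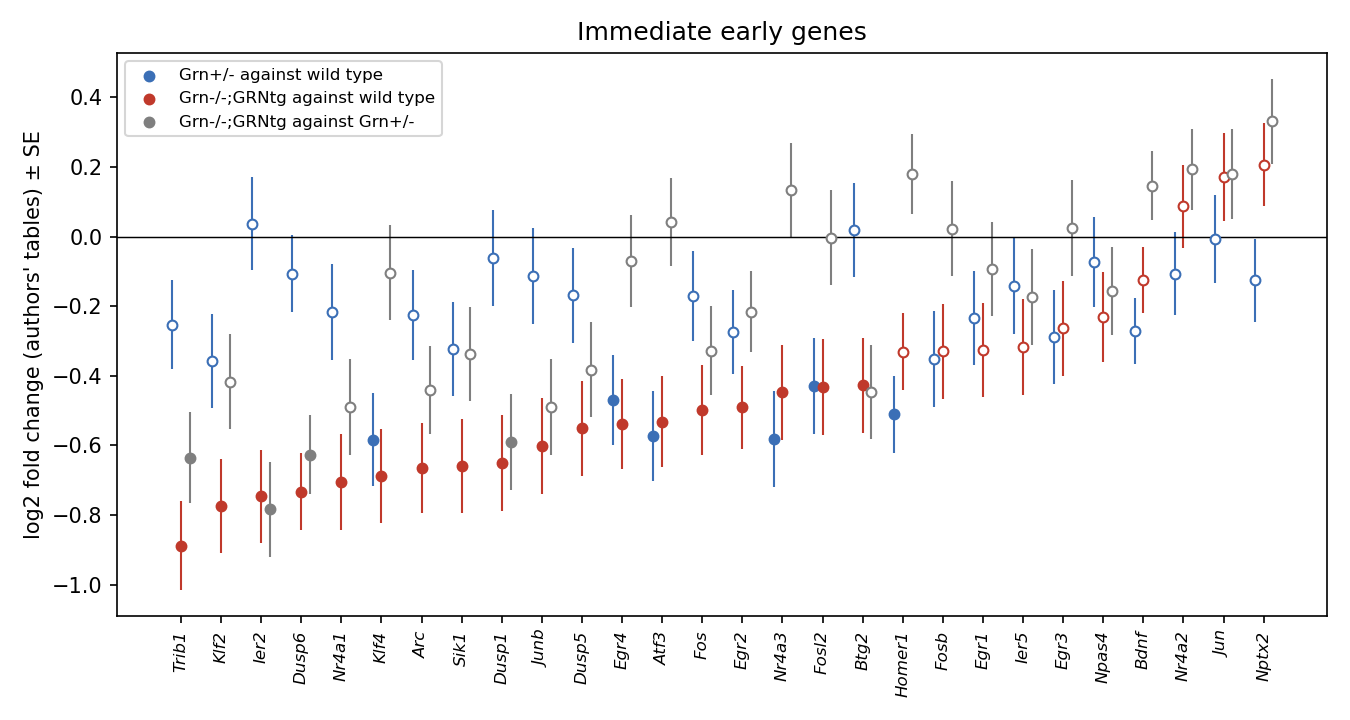
Log2 fold change ± SE of the 28 immediate early genes in the authors' deposited tables for the 3 comparisons, ordered by Grn-/-;GRNtg against wild type; filled points have an adjusted p under 0.05 and open points do not. In Grn-/-;GRNtg against wild type 25 of 28 are negative.

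Interferon response genes were lower as a list (adjusted p = 0.00017), with 27 of 28 members negative, 3 passing and 4 when adjusted over the list alone. Gbp3 (-0.55 ± 0.117), Irf9 (-0.47 ± 0.111) and Parp14 (-0.45 ± 0.133) fell in the authors' deposited table. Endothelial markers were lower (adjusted p = 0.00024) in 4 of 17 members and 6 when adjusted over the list alone, among them the receptors Flt1 (-0.36 ± 0.090), Kdr (-0.40 ± 0.117) and Eng (-0.32 ± 0.103) and the transporter Slco1c1 (-0.36 ± 0.087) in the authors' deposited table. Myelin genes were negative in 20 of 20 members (adjusted p = 0.00017), and Ugt8a, at -0.43 ± 0.137 in the authors' deposited table, was the 1 member that passed, also when adjusted over the list alone. Astrocyte markers were lower (adjusted p = 0.00080) with 2 of 16 passing, and 2 when adjusted over the list alone: Ppp1r3c at -0.36 ± 0.113 and Slc4a4 at -0.25 ± 0.080 in the authors' deposited table. Endoplasmic reticulum stress genes were lower (adjusted p = 0.0011) in 6 of 21 members and 8 when adjusted over the list alone. Pdia4 (-0.41 ± 0.085), Creld2 (-0.39 ± 0.091), Manf (-0.37 ± 0.088) and Xbp1 (-0.31 ± 0.058) fell in the authors' deposited table.

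Nuclear-retained RNAs were negative in 11 of 11 members (adjusted p = 0.0041), with Malat1 at -0.62 ± 0.109 in the authors' deposited table as the 1 that passed, also when adjusted over the list alone. Reads assigned to no gene were lower, at -0.18 ± 0.052, adjusted p = 0.024, in the authors' deposited table. Leptomeningeal markers were higher (adjusted p = 0.00078) in 21 of 22 members by sign, with 1 passing, Mgp at 0.44 ± 0.136 in the authors' deposited table, and 3 when adjusted over the list alone. Striatal markers were positive in 18 of 18 members with 0 passing, also when adjusted over the list alone (adjusted p = 0.024, 0.12 at a correlation of 0.05, and 0.061 with the gene span trend removed). Oxidative phosphorylation genes were higher with 0 of 48 passing, also when adjusted over the list alone (adjusted p = 0.0040, 0.11 at 0.05, and 0.12 with that trend removed). Cholesterol synthesis genes were higher (adjusted p = 0.043, and 0.18 at 0.05) with 1 of 22 passing, Fdft1 at 0.25 ± 0.061 in the authors' deposited table, and 1 when adjusted over the list alone.

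The microglial lists did not pass, at adjusted p = 0.32 for homeostatic and 0.84 for disease-associated genes, with 0 of 18 and 0 of 23 members passing, also when adjusted over the list alone. Axl was at -0.22 ± 0.083 and Gpnmb at 0.22 ± 0.138 in the authors' deposited table. Lysosome genes had adjusted p = 0.47 with 3 of 42 higher, Gaa (0.26 ± 0.079), Idua (0.23 ± 0.074) and Psap (0.13 ± 0.042) in the authors' deposited table, and with 3 higher and 2 lower when adjusted over the list alone. Cfp fell by 0.52 (SE 0.105) in the authors' deposited table, within a complement list at adjusted p = 0.80 that had 1 of 18 lower and 2 when adjusted over the list alone. Reactive astrocyte genes had adjusted p = 0.40, with Hspb1 (-0.50 ± 0.135) and Nes (-0.47 ± 0.129) lower in the authors' deposited table, and 1 higher and 2 lower of 20 both over all genes and adjusted over the list alone. Neighbours of Grn had adjusted p = 0.80 in the set test, which looks for a common direction. Of 42 members, 4 were higher and 3 lower, and 7 in each direction when adjusted over the list alone. Of all 14961 genes, 728 passed. Among the neighbours Arl4d fell by 0.76 (SE 0.129), Arhgap27 fell by 0.30 (SE 0.082), and Adam11 (0.41 ± 0.085) and Eftud2 (0.20 ± 0.053) rose in the authors' deposited table.

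Ahsg (0.61 ± 0.091), Adh1 (0.74 ± 0.117), Apoa1 (0.71 ± 0.114), Apoa2 (0.72 ± 0.131) and Mat1a (0.49 ± 0.092), all abundant in liver, rose in the authors' deposited table. Their mean normalized counts lay between 10.9 and 26.8, where the deposited SE may understate the error. Tceal5 (0.43 ± 0.065), 4933404O12Rik (0.47 ± 0.085) and Grid1 (0.33 ± 0.064) rose as well in the authors' deposited table. Tnfrsf25 (-0.94 ± 0.136), Fam46a (-0.78 ± 0.123), Dok6 (-0.77 ± 0.136) and Nr2e1 (-0.48 ± 0.087) fell in the authors' deposited table. Of 14961 genes, 728 passed in the authors' deposited table, 271 higher and 457 lower. With the statistics divided by their robust spread, 9 genes passed, and with a minimum absolute log2 fold change of 0.3, 454 did.

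The direct comparison of Grn-/-;GRNtg with Grn+/- asks where the mutant groups differ. Immediate early genes were lower in Grn-/-;GRNtg, in 4 of 28 members over all genes (set test adjusted p = 6.1e-08), and with 12 lower and 1 higher when adjusted over the list alone. Ier2 fell by 0.78 (SE 0.136), Trib1 by 0.63 (SE 0.131), Dusp6 by 0.63 (SE 0.115) and Dusp1 by 0.59 (SE 0.138) in the authors' deposited table. Interferon response genes were negative in 29 of 29 members (adjusted p = 1.6e-06) with 0 passing, also when adjusted over the list alone, and their median log2 fold change was -0.13. Striatal markers were positive in 17 of 19 members (adjusted p = 3.2e-05) with 0 passing, also when adjusted over the list alone. The striatum lies beside the cortex, and whether the dissections differed between the groups was not tested. Oligodendrocyte precursor genes were higher (adjusted p = 0.0041) with 0 of 15 passing and 3 when adjusted over the list alone, Cspg4 being at 0.27 ± 0.077 and Matn4 at 0.40 ± 0.115 in the authors' deposited table.

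Excitatory neuron markers were lower as a list (adjusted p = 0.019, and 0.11 at a correlation of 0.05) with 0 of 18 passing, and with 3 lower and 1 higher when adjusted over the list alone. Camk2a was at -0.18 ± 0.058, Rorb at -0.37 ± 0.129 and Bcl11b at 0.37 ± 0.132 in the authors' deposited table. Oxidative phosphorylation genes were lower (adjusted p = 0.024, 0.22 at 0.05, and 0.062 with the gene span trend removed) and choroid plexus markers were lower (adjusted p = 0.049, 0.13 at 0.05, and 0.062 with that trend removed), with 0 of 48 and 0 of 10 passing, also when adjusted over the list alone. Homeostatic microglia (adjusted p = 0.70), disease-associated microglia (0.33), lysosome (0.14), complement (0.86) and reactive astrocyte genes (0.70) did not pass, and 0 of their 18, 25, 42, 18 and 23 members passed, also when adjusted over the list alone. Neighbours of Grn had adjusted p = 0.61, and Arl4d, at -0.56 ± 0.131 in the authors' deposited table, was the 1 of 46 that passed, also when adjusted over the list alone.

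Pvrl1 was higher by 0.46 ± 0.059 in Grn-/-;GRNtg than in Grn+/-, and Cbln1, a synaptic organizer, by 0.88 ± 0.138 in the authors' deposited table. Against wild type, Pvrl1 was at -0.42 in Grn+/- (adjusted p = 5.4e-10) and at 0.04 in Grn-/-;GRNtg (adjusted p = 0.71) in the authors' deposited tables. Apoa1 (0.72 ± 0.111), Apoa2 (0.77 ± 0.128), Ahsg (0.57 ± 0.088), Mat1a (0.50 ± 0.089) and Adh1 (0.59 ± 0.114) were higher in the authors' deposited table, as were Hif3a (0.62 ± 0.137), Fndc1 (0.60 ± 0.138) and Aloxe3 (0.58 ± 0.127). Csrnp1 (-0.73 ± 0.128), 1110046J04Rik (-0.61 ± 0.138), Hprt (-0.59 ± 0.125), Gpr153 (-0.52 ± 0.120), Fam13a (-0.42 ± 0.083) and Arhgef25 (-0.28 ± 0.065) were lower in the authors' deposited table. Against wild type, Fam13a was at 0.33 in Grn+/- (adjusted p = 0.0020) and at -0.09 in Grn-/-;GRNtg (adjusted p = 0.54) in the authors' deposited tables. Of 17562 genes, 82 passed in the authors' deposited table, 56 higher and 26 lower. Without liver genes 36 passed, 15 higher and 21 lower, and 33 passed with the statistics divided by their robust spread.

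Fold changes of the mutant groups against wild type were compared over the 13482 genes in all tables. Of genes lower in each, 236 were lower in both, against 20.3 for independent lists and 105 on average for simulated unchanged groups that share controls, with genes drawn independently (highest 127). Of genes higher, 65 were shared, against 5.71 and 42.4 (highest 58), and 0 genes passed in opposite directions. Across genes, which are not independent replicates, the fold changes correlated at r = 0.671, where simulated unchanged groups gave 0.476. Their covariance was 0.0160, of which shared controls give 0.0047, so that 0.0113 was left. The wild-type mice could not be split without values per mouse, and part of the excess overlap may come from the shared controls.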

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

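Explanations were weighed with measures chosen after the results were seen. These were the gene span trend, the comparison between the mutant groups, clock genes, the liver and skin lists and genes with low counts. The covariance and reads assigned to no gene were chosen in the same way. Values per mouse were not analysed here, so single mice were not compared with the rest of their group, and the counts of changed genes were not set beside other splits of the mice.

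The direct comparison of the mutant groups found 82 genes in the authors' deposited table whose change against wild type differed between them. Of these, 49 were listed in all 3 comparisons. Against wild type, 13 of the 49 were also called in Grn+/-, 19 in Grn-/-;GRNtg and 18 in neither, with Grn called in both. Higher in Grn-/-;GRNtg there were Cbln1 (0.88), Apoa2 (0.77), Apoa1 (0.72), Hif3a (0.62), Fndc1 (0.60), Adh1 (0.59), Aloxe3 (0.58), Ahsg (0.57), Mat1a (0.50) and Pvrl1 (0.46), as log2 fold changes of the authors' deposited table. Lower were Grn (-1.36), Ier2 (-0.78), Csrnp1 (-0.73), Trib1 (-0.63), Dusp6 (-0.63), 1110046J04Rik (-0.61), Dusp1 (-0.59), Hprt (-0.59), Arl4d (-0.56), Gpr153 (-0.52), Fam13a (-0.42) and Arhgef25 (-0.28) in the authors' deposited table. Lists that differed were immediate early (adjusted p = 6.08e-08), interferon response (1.62e-06), striatum (3.17e-05), oligodendrocyte precursor (0.00405), excitatory neuron (0.0188), nuclear oxidative phosphorylation (0.0240) and choroid plexus genes (0.0488), of which the last 3 did not pass with a correlation of 0.05 (0.11, 0.22 and 0.13). Reads assigned to no gene, which no comparison of genes uses, were lower than in wild type in the authors' deposited tables. They were at -0.22 in Grn+/- and -0.18 in Grn-/-;GRNtg.

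Immediate early genes were lower in Grn-/-;GRNtg than in either other group. With the trend of the Wald statistic with gene span removed (Spearman across genes -0.15 against wild type and 0.11 against Grn+/-), the list still passed against wild type (adjusted p = 1.09e-26) and against Grn+/- (1.59e-07), which argues against the trend as the whole cause. Chance values of the shared wild-type mice cannot account for the difference between the mutant groups, where no wild-type mouse enters. There the set test gave adjusted p = 6.08e-08, with 19 of 28 members negative and 9 positive. Chance values of the Grn-/-;GRNtg mice enter both comparisons. They stay open, since the set test presets the correlation between genes and no values per mouse were analysed here. Handling or time of day at dissection may differ between groups and cannot be told apart from genotype, since no label gives them. Clock genes as a list had adjusted p = 0.115 in the set test against wild type. Of 17 members, 1 was higher and 2 lower over all genes in the authors' deposited table. When adjusted over the list alone, 1 was higher and 5 lower. The set test looks for a common direction, so it cannot decide where members move apart. A genotype effect stays open as untested.

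Liver genes were higher in Grn-/-;GRNtg: of 57 measured members of a list written after such genes were seen, 31 passed against Grn+/-, which is 31 of the 82 calls, and the median log2 fold change was 0.26; none of the brain lists held a liver member. Counts over all genes bear on chance at low counts as the whole cause. Of 6193 genes with a mean count under 100, 58 had an unadjusted p under 0.001 in the authors' deposited table, where chance gives 6.19. A Bonferroni adjustment over 17562 genes, which holds however genes depend on each other, was passed by 13. Of low-count genes outside the list, 6.34% had an unadjusted p under 0.05. These counts argue against chance as the whole cause only if the p-values of genes with few reads are valid. Their validity at small p was not tested. That 35 of the 58 and each of the 13 are on the liver list is no separate evidence, since the list was written after such calls were seen. Liver RNA in some libraries is a candidate explanation. Of the 26 members that did not pass alone, 100% were positive, which expression of these genes in the cortex would also give. Alb, abundant in liver, was at 0.06 ± 0.033 in the authors' deposited table and decides neither way. Counting error alone gives an SE of 0.0796 at its mean count, and the deposited SE lies below that, as a shrunken value would. A shrunken fold change is drawn towards 0, so the small value of Alb does not argue against a large rise. Expression in the cortex itself was not tested, and for the 25 members also listed against wild type, subtraction of the tables puts Grn+/- at a median of 0.02 from wild type, while skin genes, also from outside the brain, were higher in the same group (adjusted p = 0.00056 against Grn+/- and 0.0014 against wild type).

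Wild type stood apart from both mutant groups. The covariance of 0.0160 between the fold changes lay above the highest simulated value of 0.00498, but genes were drawn independently in the simulation, and chance differences of the shared wild-type mice that run through many genes stay open, since no correlation between genes could be estimated. Removing the trend with gene span (Spearman across genes -0.23 in Grn+/- and -0.15 in Grn-/-;GRNtg against wild type) left 92.9% of the excess covariance. A difference in RNA or library preparation of the wild-type mice cannot be told apart from genotype, since a batch would follow the groups. Reads assigned to no gene were at -0.22 in Grn+/- and -0.18 in Grn-/-;GRNtg against wild type in the authors' deposited tables. Between the mutant groups they were at 0.04. Nuclear-retained RNAs, a list fixed in advance as a sign of RNA quality, had the same pattern. They were lower in Grn+/- and Grn-/-;GRNtg against wild type (set test adjusted p = 0.00015 and 0.0041) and did not pass between the mutant groups (0.33). Cytosolic ribosome genes, the other such list with matches, did not pass in any comparison (0.87, 0.48 and 0.24).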

How the results depend on the processing

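Settings without liver genes, without Grn, with the gene span trend removed and with a prior removed were chosen after seeing the data. No paired analysis was possible because mouse numbers are shared across genotypes in the labels only and the tables hold no values per mouse. For the same reason edgeR and DESeq2 refits, count filters on libraries, pseudocounts and leaving out each mouse were not run. Counts of changed genes for Grn+/- against wild type, Grn-/-;GRNtg against wild type and between the mutant groups were 357, 254 and 35 at an adjusted p of 0.01, and 1423, 1396 and 159 at 0.1. With an empirical null they were 3, 9 and 33. This setting treats a broad shift of many genes as noise, by construction. A minimum absolute log2 fold change of 0.3 left 499 and 454 against wild type. Between the mutant groups, 36 passed at a mean count of at least 100 (14 higher, 22 lower), 43 among genes in all 3 tables (19 higher, 24 lower) and 36 without liver genes (15 higher, 21 lower), against 56 higher and 26 lower with all genes. Fewer low-count genes entered each. At a threshold of 0.1, 411 genes were lower and 177 higher in both mutant groups. With a correlation of 0.05, 5 lists passed for Grn+/- against wild type and 4 between the mutant groups, and with ranks 11 did between the mutant groups. With the gene span trend removed, the lists that lost their call were lysosome (adjusted p = 0.072) and oligodendrocyte precursor genes (0.062) in Grn+/- and oxidative phosphorylation (0.12) and striatal genes (0.061) in Grn-/-;GRNtg, against wild type, and choroid plexus (0.062) and oxidative phosphorylation genes (0.062) between the mutant groups. Heat shock genes gained one in Grn-/-;GRNtg against wild type (0.028), and endothelial genes between the mutant groups (0.042). The other counts stayed within 1.5 times, and Grn kept its direction and call in each setting. Close counts did not always hold the same members. With the gene span trend removed, 740 genes passed in Grn+/- against wild type, 644 of them among the 917. With ranks, 8 lists passed there, 7 of them among the 10 of the main setting. With fold changes in place of the statistic, 8 lists passed between the mutant groups, 5 of them among the 7 of the main setting.

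Over all settings, results of named genes kept direction and call in 2265 cases, lost the call in 150 and gained it in 24, and results of lists did so in 787, 28 and 17. No list that passed changed direction. Lists that did not pass changed sign as follows, and the cause was not tested. With fold changes in place of the statistic, neighbours of Grn gave 0.0048 in Grn+/- and oligodendrocyte precursor genes -0.010 in Grn-/-;GRNtg, against wild type. With members of a single list, oligodendrocyte precursor genes gave -0.061 against wild type in Grn-/-;GRNtg, and cytokine genes 0.00064 and blood genes -0.062 between the mutant groups. At a mean count of at least 10, hippocampal genes gave -0.11 in Grn-/-;GRNtg against wild type, and synapse genes 0.0097 and thalamic genes 0.028 between the mutant groups. With the gene span trend removed, ribosomal genes gave -0.23 in Grn-/-;GRNtg against wild type and cytokine genes 0.018 between the mutant groups. Without Grn, frontotemporal dementia genes gave 0.50, 0.84 and 0.31 in the 3 comparisons, since Grn is a member.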

Other observations

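The tests of skin, skeletal muscle, kidney and pancreas genes and of a prior on fold changes were chosen after the results were seen. Clock genes did not pass as a list in any comparison (adjusted p = 0.47, 0.11 and 0.33). The set test looks for a common direction, so it cannot decide where members move apart. Of all genes, 917 of 13482, 728 of 14961 and 82 of 17562 passed in the 3 comparisons in the authors' deposited tables. In Grn+/- against wild type, 3 of 17 members were higher (Dbp, Nr1d1 and Ciart) and 2 lower (Clock and Per2) in the authors' deposited table, and as many when adjusted over the list alone. In Grn-/-;GRNtg against wild type, 1 was higher (Dbp) and 2 lower (Per1 and Bhlhe40) in the authors' deposited table, and 1 higher and 5 lower when adjusted over the list alone, while between the mutant groups none passed either way. These clock genes are named after their values were seen. Synapse genes did not pass as a list in Grn+/- against wild type (adjusted p = 0.70) and held members that moved apart, with 2 higher and 4 lower of 30 over all genes, and 6 in each direction when adjusted over the list alone. Of the lists of other tissues added later, skin genes were higher in Grn-/-;GRNtg than in Grn+/- (adjusted p = 0.00056, median log2 fold change 0.23, 1 of 10 passing) and than in wild type (0.0014, median 0.31, 2 of 8 passing), but not in Grn+/- against wild type (0.97). The members that passed, named after their values were seen, were Krt2 in both and Evpl against wild type in the authors' deposited tables. Skeletal muscle (adjusted p = 0.96, median 0.0038) and kidney genes (0.93, median 0.019) did not pass against Grn+/-, and pancreas genes, with 4 measured, were not tested.

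The deposited SEs have a ceiling of 0.138, which is consistent with a zero-centred prior that shrinks fold changes. A test of this hypothesis used group sizes: with 5 wild-type and 4 Grn+/- mice of equal spread, the variance of the wild-type mean over that of the Grn+/- mean is 0.8. Among genes with SEs from 0.11 to 0.13 the deposited SEs gave a median ratio of 0.904, and 0.797 with such a prior removed. If so, the log2 fold change of Grn is -0.71 in Grn+/- and -2.23 in Grn-/-;GRNtg, which is 61.0% (95% interval 54.4 to 68.3) and 21.3% (18.8 to 24.1) of wild type. Whether the remaining Grn signal in Grn-/-;GRNtg comes from the mouse allele or from reads of the human transgene was not tested.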
